A study of Mus musculus with 34 samples.

How the data were processed

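RNA sequencing values of 34 mouse liver tumor and liver libraries were analysed from 3 deposited tables, for 16 mixed-strain tumor libraries, 12 FVB tumor libraries and 6 libraries from Rag1-/- livers. Per the labels, RNA was taken from frozen tissue with Trizol and a miRNeasy kit, and libraries were made with a Nugen kit. Whether that kit kept strand, and which counting mode was used, are not given in the sources used here. The submitters' processing notes name Trim Galore, HISAT2, SAMtools and featureCounts and the mouse build GRCm38 (mm10), without versions.

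All 3 tables hold log2 values that the authors deposited. The FVB and Rag1-/- tables were deposited as normalized log2 CPM (read counts scaled to a common library total), with genes at or below 1 CPM in a library listed at 0. The deposited FVB table has 16140 genes and the one for Rag1-/- livers has 14074, each with at least 1 CPM in some library. The mixed-strain table has 46528 genes and is named by the authors as RPKM, but its deposited log2 values, after back-transformation with 1 subtracted, summed to 999553 to 999898 per library and moved in steps of equal size for all genes, as log2(CPM + 1) does and RPKM does not. They were therefore used as CPM. A test planned on log2(RPKM + 0.5) with a mean RPKM of at least 0.5 was run on log2(CPM + 0.5) with a mean CPM of at least 0.5, which left 17552 genes. There, 27 symbols were turned into dates and are not named. A fold change there is on the log2(CPM + 0.5) scale, and a fold change in the other 2 tables is on the floored log2 CPM scale, so both understate the change of genes near the floor. The floor also narrows the spread of such genes, which can help them pass. Every gene of the FVB and Rag1-/- tables passed the planned filter of a mean log2 CPM of at least 0.

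Low values in each library were whole multiples of what 1 read is worth, within a tolerance of 0.1 reads for 100% of the low values examined. This gave 2.28 to 5.29 M reads per mixed-strain library (median 4.01), 6.64 to 12.0 per FVB library (median 9.41) and 8.73 to 10.6 per Rag1-/- library (median 9.12). Higher values were too coarsely rounded to give whole reads, so no count test was run. In the deposited tables the most abundant gene took 0.130% to 0.544% of a mixed-strain library (Apob), 7.32% to 14.0% of an FVB library (Gm26917) and 3.66% to 4.60% of a Rag1-/- library (Alb). Replicate pairs within a group all differed by more than sampling noise. Over genes with at least 100 reads, the median ratio of observed to sampling variance ran from 2.43 to 28.1 over the pairs, so no library was treated as a copy of another.

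Samples were grouped by the genotype, strain and virus in the labels. The treatment text of the labels gives the Het and Homo genotypes in the same words, so the genotype field was used, which gives fl/+ for Het and fl/fl for Homo. The labels call the 3 ad-ARID1A libraries by the names of ad-Cre columns, while the table has ad-ARID1A columns of the same numbers, and these were matched by number. The labels give no batch and do not say that each sample came from a separate mouse, so p-values measure only the spread between these samples.

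Each table was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), because the tables were normalized separately. The 3 FVB groups shared a single fit. There were 5 comparisons: mixed-strain Het against WT, FVB Het against WT, FVB Homo against WT, FVB Homo against Het, and ad-ARID1A against ad-Cre. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All p-values are two-sided. A gene was called separated when every library of one group lay above every library of the other.

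Gene lists for 26 pathways and cell types were fixed before the data were examined. They covered the study's own 4 genes, cytochrome P450 drug metabolism, glutathione and oxidative stress, SWI/SNF subunits other than Arid1a, hepatocyte function, oncofetal liver tumor markers, cell cycle, MYC-linked ribosome biogenesis, invasion and matrix remodeling, acute phase and inflammation, interferon response, p53 targets, bile acid synthesis and transport, lipogenesis and sterol synthesis, fatty acid oxidation and PPAR targets, immediate early and heat shock genes, and hypoxia and glycolysis. They also covered markers of biliary and progenitor cells, macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils, stellate cells and fibroblasts, endothelial cells, erythroid cells and pancreatic acinar cells. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of the comparison. Camera with an estimated correlation and limma's fry were run beside it. Members were counted as passing over all genes and, separately, adjusted over the list alone. The 4 genes of the study, and its interest in P450 genes, came from work by the authors on these or sibling samples, so neither list is independent evidence of its direction.

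The genes named were chosen by a rule fixed in advance with the designs and the alternatives. It takes Arid1a, Myc, Emilin1, Mat1a, Lcn2 and Il1r1 in every comparison. It adds up to 8 higher and 8 lower genes with the largest changes among those that passed, were separated and reached a log2 CPM of 1 in the higher group, predicted genes left out. It adds up to 4 members with the smallest p of each called list, of which the first 2 are used here. Where fewer than 3 genes qualified, the 5 genes with the smallest p are given as values only. Gene positions are from the GENCODE vM21 annotation of GRCm38. A gene that the rule picks in the FVB comparisons is not reported here, on an instruction from outside the analysis and not because of its value, and it stays among the genes tested. Of the other 191 genes the rule can name, 48 share exon sequence positions with another gene, and without known strand such reads cannot be assigned with certainty. Reads of near-identical family members (Cyp2a, Cyp2b, Cyp2c, Orm, Saa, Apol9, histone and hemoglobin genes) are uncertain in the same way.

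The fits were tested on simulated values, drawn independently for each gene from its mean and within-group spread in the real tables. In them 200 genes were changed by known folds, 50 per fold size. These were picked among genes with a mean CPM (mixed-strain) or mean log2 CPM (other tables) of at least 2. Recovery of lower genes was therefore not tested. At a change of 1.5-fold, 28% of the changed genes were recovered in the mixed-strain comparison, 18% in FVB Het against WT, 32% in FVB Homo against WT, 26% in FVB Homo against Het and 30% in ad-ARID1A against ad-Cre. At 2-fold these shares were 64%, 72%, 76%, 76% and 64%, and at 4-fold 90%, 96%, 94%, 90% and 98%. In the same order 6, 13, 3, 9 and 5 unchanged genes were called, among 145, 153, 152, 153 and 149 calls. The real fits called 28, 4, 7, 0 and 45 genes. With fewer calls the adjusted threshold is stricter, so these shares can overstate recovery in the real comparisons.

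Alternatives covered the pseudocount, the filter on low values, a term for 2 runs of library numbers in the mixed-strain labels, the replicate number as a block, quantile normalization, eBayes without the trend, array weights, a covariate for sex built from Xist and 4 Y-linked genes (the labels do not give the sex of the mice), fits of only the groups compared, and leaving out each library in turn. Each count of genes and lists was set against other splits of the same libraries, all of them where there were at most 35 and 100 drawn at random otherwise.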

Results

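Gene expression was measured by RNA sequencing in liver tumors of mice that carry a MYC transgene under a liver-restricted tetracycline switch (LAP-tTA; TRE-MYC), in which tumors form once doxycycline is withdrawn. Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodeling complex. WT tumors carried floxed Arid1a without Cre, Het tumors a single floxed allele with the hepatocyte-expressed Alb-cre, and Homo tumors floxed alleles on both copies with Alb-cre. A mixed-strain background that includes C57/B6 and FVB gave 8 WT and 8 Het tumors from mice about 90 days old. An FVB background gave 4 WT tumors at about 55 days, 4 Het tumors at about 70 days and 4 Homo tumors at about 100 days. All of these were taken at death, so that age moved with genotype in FVB. The presence of Cre moved with genotype in every comparison with WT tumors, mixed-strain and FVB, and cannot be told apart from loss of Arid1a there. A gain-of-function set came from Rag1-/- mice with the MYC transgenes, which lack mature lymphocytes, at about 42 days of age. Their livers were taken 14 days after an adenovirus that carried human ARID1A (ad-ARID1A, 3 livers) or Cre (ad-Cre, 3 livers). The sample titles call these livers WT. Virus-borne Cre was given to the control livers alone, so added ARID1A and the absence of that Cre cannot be told apart. The median depth was 4.01 M reads in the mixed-strain libraries (2.28 to 5.29), 9.41 M in the FVB libraries and 9.12 M in the Rag1-/- libraries, so low genes were least precise in the mixed-strain set. Values below are log2 CPM, given as mean ± SD, and log2 fold changes with their standard errors (SE).

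Arid1a (chromosome 4, 133679008 to 133756769, minus strand, GRCm38) was reported first to check the labels. In the mixed-strain tumors its level was 8.47 ± 0.21 in WT (n = 8) and 8.07 ± 0.14 in Het (n = 8), a log2 fold change of -0.41 ± 0.09 SE that missed the threshold over all genes (limma adjusted p = 0.083). The 8 Het libraries lay between 7.97 and 8.37 and the 8 WT libraries between 8.30 and 8.94. In FVB the level was 8.09 ± 0.25 in WT, 7.76 ± 0.31 in Het and 7.74 ± 0.23 in Homo tumors (n = 4 each), with differences from WT of -0.32 ± 0.17 SE (adjusted p = 0.424) and -0.35 ± 0.17 SE (adjusted p = 0.515). The gene's level did not separate Homo from Het tumors (difference -0.03 ± 0.17 SE). The lowest library was 7.43 in Homo and 7.53 in Het. The labels do not say which exon is deleted and the value counts reads over the whole gene. Tumor samples also hold cells without Cre, so this level is a weak check of the labels. In the Rag1-/- livers the mouse gene was at 6.84 ± 0.02 after ad-Cre and 6.99 ± 0.22 after ad-ARID1A (n = 3 each, difference 0.15 ± 0.11 SE, adjusted p = 0.619). The human ARID1A carried by the virus has no entry of its own in the mouse table, so its delivery could not be checked.

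Myc (chromosome 15, 61985391 to 61990374) did not pass in any comparison. Its log2 fold change was -0.19 ± 0.31 SE in mixed-strain Het tumors, 0.04 ± 0.20 SE in FVB Het and 0.01 ± 0.20 SE in FVB Homo tumors against WT. After ad-ARID1A it was 2.98 ± 0.79 against 4.38 ± 0.55 after ad-Cre, a separated difference of -1.40 ± 0.38 SE that missed the threshold over all genes (adjusted p = 0.175). Whether reads of the transgene are counted in this mouse gene is not given in the sources used here.

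**Figure D1:**
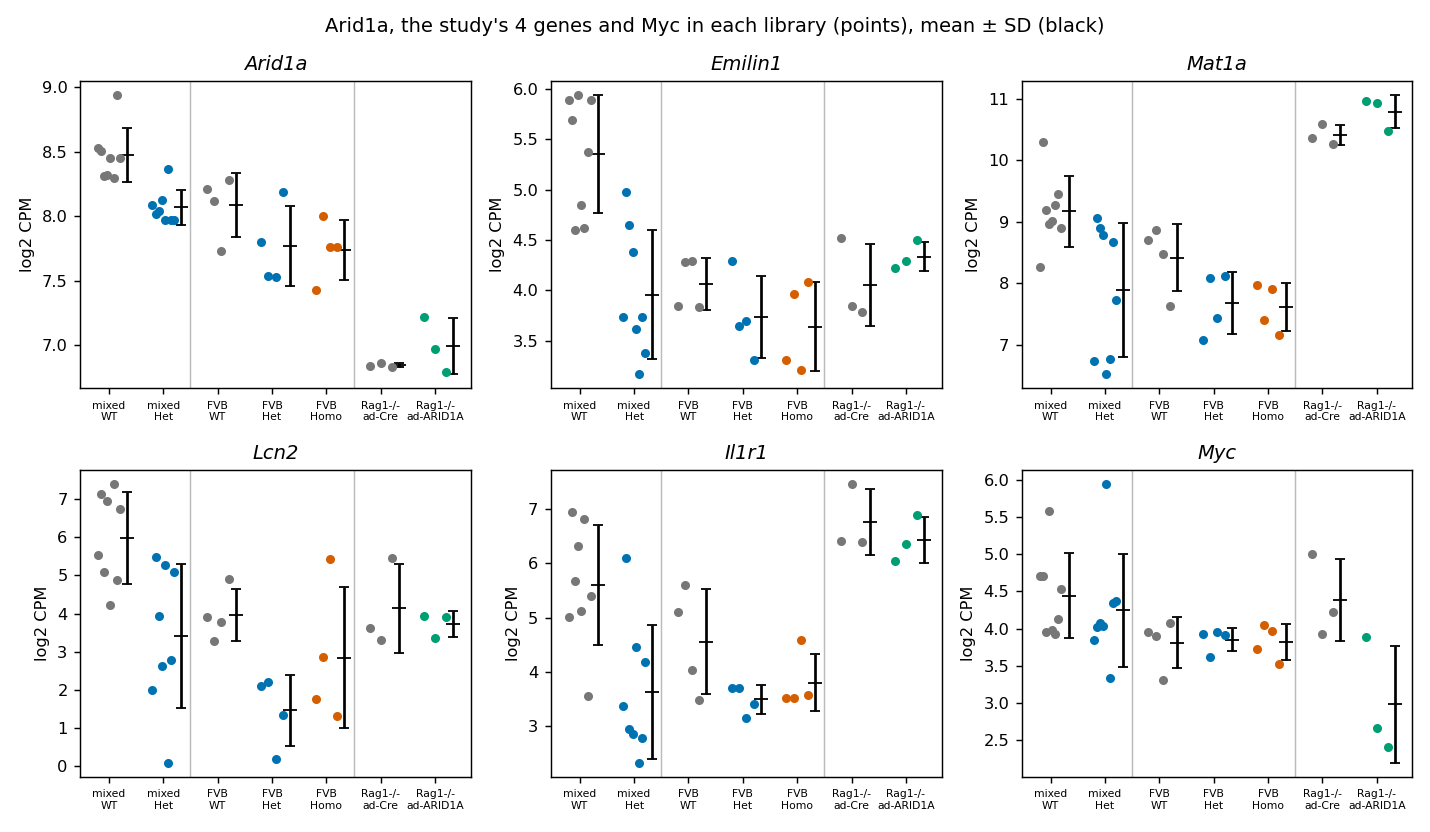
Log2 CPM of Arid1a, Emilin1, Mat1a, Lcn2, Il1r1 and Myc in each of the 34 libraries (points), with the group mean ± SD in black; the vertical lines part the 3 tables, which were normalized separately. Arid1a averaged 8.47 in mixed-strain WT and 8.07 in mixed-strain Het tumors, and Emilin1 5.35 and 3.96.

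Mixed-strain Het tumors were compared with WT tumors to ask how expression differs with loss of a single Arid1a copy, which came together with Cre. Of 17552 genes tested 28 changed, 7 higher and 21 lower in Het. Among the separated genes, the largest falls were in Cyfip2 (-2.89 ± 0.33 SE, adjusted p = 0.000662), a subunit of the WAVE complex that controls actin assembly, and Pkdcc (-2.70 ± 0.26 SE, adjusted p = 0.000108), a secreted tyrosine kinase. Cyfip2 (chromosome 11, 46193850 to 46312859) fell from 8.16 ± 0.37 to 5.27 ± 0.99 and Pkdcc (chromosome 17, 83215292 to 83225070) from 5.92 ± 0.47 to 3.22 ± 0.65 (n = 8 each). P2ry14, a receptor for UDP-sugars, fell by 1.58 ± 0.19 SE (adjusted p = 0.00095), and Cd163, a hemoglobin scavenger receptor of macrophages, by 2.25 ± 0.41 SE. D16Ertd472e, Tuba8, Aspdh and Dmpk fell by 2.67, 2.07, 1.28 and 1.19. Cd109 (1.94 ± 0.37 SE, adjusted p = 0.0404), a surface protein that binds TGF-beta, and the protocadherin Pcdh19 (1.71 ± 0.30 SE, adjusted p = 0.0256) rose. Tuba8 and Pcdh19 share exon positions with antisense genes.

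The liver metabolism lists lay lower in mixed-strain Het tumors. In the cytochrome P450 list 30 of 31 measured members were lower, 0 passed over all genes and 19 passed adjusted over the list alone, with a median of -2.08 (camera adjusted p = 2.61e-17; adjusted p = 0.126 with an estimated correlation). Cyp2a5 (-3.35 ± 0.80 SE), which hydroxylates coumarin, and Cyp2c39 (-3.54 ± 0.86 SE) had the smallest p-values of the list. Bile acid genes were lower in 18 of 18 members, 11 adjusted over the list alone, with a median of -1.64 (camera adjusted p = 1.16e-11; adjusted p = 0.126 with an estimated correlation). They were led by the oxysterol hydroxylase Cyp39a1 (-2.53 ± 0.57 SE) and the hepatocyte uptake transporter Slco1b2 (-3.02 ± 0.78 SE). Markers of hepatocyte function moved with them, 36 of 37 lower and 11 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 1.31e-13; adjusted p = 0.126 with an estimated correlation). Among them were the apolipoprotein Apoc3 (-2.40 ± 0.57 SE) and Hpd of tyrosine breakdown (-1.48 ± 0.37 SE). Acute phase genes were lower in 25 of 27 members, 9 adjusted over the list alone, with a median of -1.19 (camera adjusted p = 6.48e-11; adjusted p = 0.126 with an estimated correlation). The smallest p-values were those of the iron hormone Hamp (-2.80 ± 0.67 SE) and haptoglobin, Hp (-2.52 ± 0.64 SE). The lipogenesis list had 20 of 27 members lower and a median of -0.24, 2 of them adjusted over the list alone, Srebf1 (-0.75 ± 0.18 SE) and Thrsp (-2.53 ± 0.72 SE). The glutathione list had 19 of 28 members lower, 0 of them adjusted over the list alone, and a median of -0.13, with Sod3 at -1.01 and Gstt1 at -0.66. The tests of these 2 lists gave a camera adjusted p of 0.000301 and 0.00659, and an adjusted p = 0.487 and 0.436 with an estimated correlation.

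The study's own genes, Emilin1 (-1.40 ± 0.28 SE, adjusted p = 0.0627), Mat1a (-1.28 ± 0.39 SE, adjusted p = 0.157), Lcn2 (-2.58 ± 0.70 SE, adjusted p = 0.133) and Il1r1 (-1.97 ± 0.52 SE, adjusted p = 0.125), were all lower in mixed-strain Het tumors. None of the 4 passed over all genes and all 4 passed adjusted over the list alone (camera adjusted p = 2.97e-06; adjusted p = 0.108 with an estimated correlation; fry adjusted p = 0.00727). The authors chose these genes on such samples, so their direction is not independent evidence. Emilin1 encodes an elastin-associated matrix protein, Mat1a the liver's methionine adenosyltransferase, Lcn2 an iron-binding lipocalin and Il1r1 the interleukin-1 receptor.

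Marker lists of other cells also differed in the mixed-strain set. Neutrophil markers were lower in 11 of 11 members, 7 adjusted over the list alone, with a median of -1.72, including S100a8 (-2.86 ± 0.63 SE) and S100a9 (-2.71 ± 0.70 SE), which form calprotectin. Endothelial markers (median -0.44, 9 of 13 lower and 5 adjusted over the list alone) included the sinusoidal genes Stab2 (-1.54 ± 0.34 SE) and Oit3 (-2.25 ± 0.59 SE). Stellate cell and fibroblast markers (median -0.28, 11 of 14 lower and 3 adjusted over the list alone) included Lrat (-2.20 ± 0.60 SE), which stores retinol as esters, and Pdgfra (-2.23 ± 0.61 SE). Macrophage and Kupffer cell markers had a median of -0.11, with 9 of 14 lower and 3 adjusted over the list alone, among them the Kupffer cell genes Clec4f (-3.42 ± 1.01 SE) and Marco (-2.23 ± 0.70 SE). Erythroid markers (9 of 9 lower, median -0.90, Slc4a1 -2.10 and Hbb-bt -0.94) and oncofetal markers (15 of 18 lower, median -0.26, Golm1 -0.61 and Igf2 -0.26) had 0 members adjusted over the list alone. Camera adjusted p-values of these 6 lists ran from 1.22e-07 to 0.0313, and with an estimated correlation the smallest was an adjusted p = 0.126 and the largest an adjusted p = 0.597.

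Of the lists that lay higher in mixed-strain Het tumors, the cell cycle list had 40 of 43 members higher and a median of 0.22, with Kif23 (0.93 ± 0.22 SE), a kinesin of cytokinesis, adjusted over the list alone and Kif20a at 0.54 ± 0.15 SE. Ribosome biogenesis genes were higher in 27 of 31 members, with a median of 0.22, Noc4l at 0.41 ± 0.13 SE and Polr1b at 0.44 ± 0.16 SE. Interferon response genes were higher in 22 of 27 members, with a median of 0.73, Oasl1 at 1.52 ± 0.56 SE and Mx1 at 1.35 ± 0.53 SE. The SWI/SNF list had 17 of 23 members higher and a median of 0.21, although its first member by p-value, Dpf3, was at -0.65 ± 0.20 SE and the second, Smarcc1, at 0.42 ± 0.14 SE. Apart from Kif23, 0 members of these 4 lists passed over all genes or adjusted over the list alone. Their camera adjusted p-values were 1.31e-06, 3.46e-05, 0.00659 and 0.00659, against an adjusted p = 0.487, 0.487, 0.606 and 0.436 with an estimated correlation.

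In all, 17 of 25 lists were called in the mixed-strain comparison at the preset correlation, 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 1 by fry, the study's genes. The count of 28 changed genes depended on single libraries. It was 8 to 18 without WT 1, 3, 5, 6 or 8 or Het 1, 3, 4 or 6, and 48, 65 and 138 without WT 7, Het 7 and Het 2. It was 14 with no filter on low values and 16 without WT 2 and Het 5, which stood apart on the first 2 principal components. Without these 2 libraries the P450 median was -1.34 and the hepatocyte median -0.37, and the glutathione, macrophage and stellate lists were not called. Interferon genes were not called without Het 5 alone (median 0.34, camera adjusted p = 0.369) and were called without Het 5 and WT 2 (median 0.56, camera adjusted p = 0.0207). The glutathione list was not called without WT 2, nor the macrophage list without any 1 of 6 libraries.

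**Figure D2:**
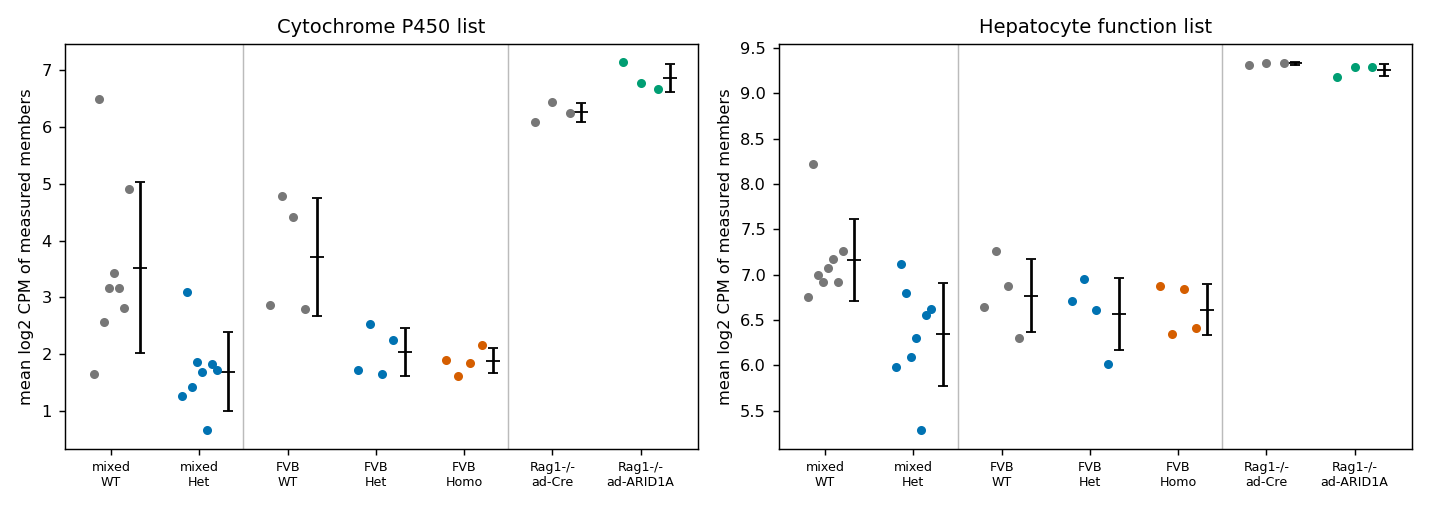
Mean log2 CPM of the measured members of the cytochrome P450 list (left) and the hepatocyte function list (right) in each library (points), with the group mean ± SD in black; vertical lines part the 3 separately normalized tables. The P450 mean was 3.52 in mixed-strain WT and 1.69 in mixed-strain Het tumors, 3.71 in FVB WT, 2.04 in FVB Het and 1.88 in FVB Homo tumors, and above 6 in both groups of Rag1-/- livers.

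FVB Het tumors were compared with FVB WT tumors as the same genotype contrast in a single strain. Of 16140 genes 4 changed, all lower in Het and all separated. Orm1 (chromosome 4, 63344560 to 63348163), an acute phase glycoprotein, fell by 2.70 ± 0.40 SE (adjusted p = 0.0465), from 2.96 ± 0.79 to 0.26 ± 0.31 (n = 4 each). Lrat (chromosome 3, 82892579 to 82903973), the retinol-esterifying enzyme that marks stellate cells, fell by 2.50 ± 0.31 SE (adjusted p = 0.0234), from 2.57 ± 0.32. Apol9a fell by 2.04 ± 0.29 SE and the histone gene Hist1h2bl by 1.23 ± 0.18 SE (both adjusted p = 0.0465). Lrat and Apol9a were listed at 0 in 3 of 4 Het libraries and Orm1 in 2 of 4, so these falls are understated. The floor also narrows the spread of these genes in Het tumors, which can help them pass. With a mean log2 CPM of at least 2, 0 genes passed.

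The P450 list was again the list with the smallest camera p. All 27 measured members were lower in FVB Het tumors, 0 passed over all genes and 17 passed adjusted over the list alone, with a median of -1.65 (camera adjusted p = 5.09e-17; adjusted p = 0.241 with an estimated correlation). Cyp2j5 (-2.25 ± 0.45 SE), an arachidonic acid epoxygenase, and Cyp2c29 (-3.06 ± 0.69 SE) led it. The median of the hepatocyte function genes did not move with them in FVB Het tumors, with 16 of 37 members lower, a median of 0.05 and a mean of -0.20 (camera adjusted p = 0.605, direction lower). Many of these genes are high in tumors, which limits what the median can show. Members far below their level in ad-Cre livers fell, such as Tat (mean CPM 42.2 to 14.8), Fbp1 (28.2 to 6.80) and Alb (3057 to 1532). The fall was therefore not particular to P450 genes. Bile acid genes were lower in 15 of 18 members, 5 adjusted over the list alone, with a median of -0.58, including Cyp7a1 (-2.11 ± 0.61 SE), the rate-limiting enzyme of bile acid synthesis, and Slco1b2 (-1.88 ± 0.57 SE). Acute phase genes were lower in 17 of 23 members, Orm1 over all genes and 8 adjusted over the list alone, with a median of -0.91 and the heme-binding Hpx at -1.66 ± 0.31 SE. The study's genes stood at -0.33 (Emilin1), -0.74 (Mat1a), -2.50 (Lcn2) and -1.06 (Il1r1). Of these 0 passed over all genes and Mat1a, Lcn2 and Il1r1 passed adjusted over the list alone, which is not independent evidence. Camera adjusted p-values of these 3 called lists were 0.000358, 1.34e-05 and 0.00199, against an adjusted p = 0.491, 0.45 and 0.178 with an estimated correlation.

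Fatty acid oxidation genes went the other way in FVB Het tumors, higher in 23 of 23 members with a median of 0.41. None of the 23 passed over all genes and 7 passed adjusted over the list alone, led by the lipase inhibitor Angptl4 and the thioesterase Acot1 (0.63 ± 0.17 SE), both targets of the receptor PPAR-alpha (camera adjusted p = 9.27e-08; adjusted p = 0.485 with an estimated correlation). Erythroid markers were lower in 9 of 9 members, 5 adjusted over the list alone, with a median of -2.01, Epb42 at -2.61 ± 0.78 SE and Hbb-bs at -2.44 ± 0.77 SE. Neutrophil markers were lower in 10 of 11 members with 0 adjusted over the list alone, a median of -1.34, Ltf at -2.46 ± 0.94 SE and Csf3r at -1.18 ± 0.49 SE. Stellate markers (11 of 14 lower, median -0.33) included Lrat over all genes and Reln (-1.79 ± 0.42 SE) adjusted over the list alone. Endothelial markers (10 of 13 lower, median -0.26) included Clec4g (-1.49 ± 0.34 SE) adjusted over the list alone and Stab2 at -1.17 ± 0.42 SE. Interferon genes (24 of 27 lower, median -0.42, Ifih1 -0.99 and Isg15 -1.37), invasion and matrix genes (21 of 30 lower, median -0.21, Tgfbi -1.01 and Cdh1 0.61) and cell cycle genes (31 of 43 lower, median -0.13, led by Ccne1, with Ccnd1 at -1.30) had 0 members adjusted over the list alone. Camera adjusted p-values of these 7 lists ran from 4.52e-06 to 0.0443, and with an estimated correlation the smallest was an adjusted p = 0.485 and the largest an adjusted p = 0.85.

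In all, 12 of 25 lists were called in FVB Het tumors, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by fry (5 at an unadjusted p under 0.05). The count of 4 was 0 with a mean log2 CPM of at least 2 (limma, 1689 genes at an unadjusted p under 0.05) and 2287 with array weights. Leaving out single libraries gave 0 genes without WT 2, Het 2 or Het 3 (1546, 1722 and 1634 at an unadjusted p under 0.05), 1 without WT 3, 21 without WT 1, 169 without Het 4 and 256 without WT 4. Without FVB WT 1 and 2, which stood apart on the first principal component, 1 gene passed, none of the 4. Erythroid markers were then not called (median -0.22, camera adjusted p = 0.0741), nor were neutrophil (median 0), endothelial (-0.05), invasion (0) and cell cycle genes (0.025), while the P450 median was -1.53. Cell cycle, invasion and endothelial lists also lost their call without some single libraries.

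FVB Homo tumors were compared with FVB WT tumors for loss of both Arid1a copies. Of 16140 genes 7 changed, 2 higher and 5 lower, all separated. Cyp2j5 (chromosome 4, 96628773 to 96664154) fell by 3.49 ± 0.45 SE, from 3.65 ± 1.09 to 0.17 ± 0.20, the acyl-CoA synthetase Acsm1 by 3.09 ± 0.46 SE and the alcohol dehydrogenase Adh4 by 2.75 ± 0.40 SE (n = 4 each, adjusted p = 0.0297 for each). Orm1 fell by 2.64 ± 0.40 SE (adjusted p = 0.0328), and Apol9a was listed at 0 in all 4 Homo libraries against 2.10 ± 0.62 in WT (adjusted p = 0.0297). The floor leaves Apol9a no spread in Homo tumors, which can help it pass. The immunoglobulin constant genes Igkc (2.44 ± 0.36 SE) and Igha (2.24 ± 0.32 SE) rose (adjusted p = 0.0297 for each), Igkc from 0.74 ± 0.49 to 3.19 ± 0.64.

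The P450 list was lower in 26 of 27 members in FVB Homo tumors, with Cyp2j5 over all genes, 17 adjusted over the list alone and a median of -1.72 (camera adjusted p = 1.46e-17; adjusted p = 0.224 with an estimated correlation). Cyp2c29 stood at -3.52 ± 0.69 SE, and many P450 genes were near 0 in Homo tumors, which understates their falls and narrows their spread. Hepatocyte function genes had a median of 0.19 and a mean of -0.15, with 14 of 37 lower (camera adjusted p = 0.344, direction higher). The same limit of the median holds here. Tat (mean CPM 42.2 to 8.56) and Tdo2 (42.3 to 4.86) fell, while Ahsg (636 to 762) and Serpina1a (114 to 131) rose. The bile acid list had 10 of 18 members lower, 5 adjusted over the list alone, a median of -0.18 and a mean of -0.75 (camera adjusted p = 0.00736; adjusted p = 0.733 with an estimated correlation). The transporters Slco1b2 (-2.71 ± 0.57 SE) and Slco1a1 (-3.02 ± 0.70 SE) were among the 5. Stellate cell and fibroblast markers were lower in 14 of 14 members, 5 adjusted over the list alone, with a median of -0.95, including Lrat (-1.78 ± 0.31 SE) and Reln (-1.87 ± 0.42 SE) (camera adjusted p = 4.3e-07; adjusted p = 0.327 with an estimated correlation). B and plasma cell markers were higher in 4 of 5 members with a median of 0.92, Igkc over all genes and Jchain (1.47 ± 0.41 SE), the joining chain of IgA and IgM, adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.327 with an estimated correlation). The study's genes were at -0.42 (Emilin1), -0.81 (Mat1a), -1.12 (Lcn2) and -0.75 (Il1r1), 0 passing over all genes or adjusted over the list alone, and the list is not independent evidence (camera adjusted p = 0.0122; adjusted p = 0.224 with an estimated correlation).

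The other called lists in FVB Homo tumors held 1 member adjusted over the list alone, Clec4g (-1.42 ± 0.34 SE) among the endothelial markers, which were lower in 10 of 13 members with a median of -0.37 and Stab2 at -1.22 ± 0.42 SE. Erythroid markers (9 of 9 lower, median -1.07, led by Epb42 at -2.33), cell cycle genes (36 of 43 lower, median -0.17, Ccnd1 -1.67 and Kif23 -0.46) and SWI/SNF subunits (19 of 23 lower, median -0.08, Smarca2 -0.92 and Smarcd2 -0.24) were called lower. Immediate early genes (15 of 18 higher, median 0.33, led by Zfp36, with Junb at 1.14) and hypoxia genes (17 of 20 higher, median 0.20, Bnip3 0.45 and Egln3 0.83) were called higher. Camera adjusted p-values of these 6 lists ran from 0.000791 to 0.0452, and with an estimated correlation the smallest was an adjusted p = 0.733 and the largest an adjusted p = 0.825. In all, 11 of 25 lists were called, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by fry (4 at an unadjusted p under 0.05). The 7 changed genes were 0 with a mean log2 CPM of at least 2, with only the 2 groups in the fit, or with the sex covariate (limma, 1117, 1336 and 1234 genes at an unadjusted p under 0.05). Leaving out single libraries gave 24 genes without WT 1, 36 without WT 4 and 0 without WT 2, WT 3, Homo 1, Homo 2 or Homo 4 (981, 2311, 1356, 1594 and 1668 at an unadjusted p under 0.05). Without FVB WT 1 and 2, 3 genes passed, 1 of them among the 7, and the erythroid median was 0.45, the reverse of its direction with all libraries. Of the 11 lists 3 stayed called then, P450, stellate cells, and B and plasma cells. Leaving out single libraries lost the call of SWI/SNF, immediate early, hypoxia, endothelial, cell cycle and bile acid genes and of the study's genes in 1 or more runs.

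FVB Homo and Het tumors were compared directly, as the test of whether their effects differ. Of 16140 genes 0 changed (limma, 623 at an unadjusted p under 0.05). The 5 genes with the smallest p were Gm13123 (-1.65 ± 0.28 SE, adjusted p = 0.792), Polr2l (1.44 ± 0.28 SE), Nhs (-1.53 ± 0.31 SE), Gm11405 (1.25 ± 0.27 SE) and Psma8 (-2.38 ± 0.53 SE), the last 4 with an adjusted p of 1. Emilin1, Mat1a, Lcn2 and Il1r1 stood at -0.10, -0.07, 1.38 and 0.31, and Myc at -0.04. Fatty acid oxidation genes were lower in Homo than in Het tumors in 23 of 23 members, with a median of -0.42, Acot1 (-0.66 ± 0.17 SE) and Cpt1a (-0.47 ± 0.13 SE), the gatekeeper of mitochondrial fatty acid entry, adjusted over the list alone (camera adjusted p = 2.03e-08; adjusted p = 0.902 with an estimated correlation). Neutrophil markers were higher in 11 of 11 members with a median of 1.03, of which Csf3r (1.80 ± 0.49 SE) passed adjusted over the list alone and Ltf stood at 1.45 (camera adjusted p = 3.62e-06; adjusted p = 0.902 with an estimated correlation). Acute phase genes (21 of 23 higher, median 0.24, Apcs 0.77 and Hamp 1.42), interferon genes (23 of 27 higher, median 0.20, Usp18 0.73 and Bst2 0.20) and erythroid markers (8 of 9 higher, median 0.50, Hbb-bs 1.20 and Slc4a1 1.88) had 0 members adjusted over the list alone and camera adjusted p-values of 1.77e-05, 0.00113 and 0.0194. None of these 5 called lists held 1 member over all genes, and each had an adjusted p = 0.902 with an estimated correlation; fry called 0 lists (0 at an unadjusted p under 0.05). The neutrophil result rested on Homo 3, without which the median was 0 (camera adjusted p = 0.605), and the erythroid and acute phase lists were then not called either (0.21 and 0.13, camera adjusted p = 0.605 and 0.111). Interferon genes were not called without Homo 1 (median 0.09) or Homo 2 (median 0.12), which leaves fatty acid oxidation as the 1 list called without any single library. The count of 5 lists was 9 without Het 1, 8 without Homo 1 and 10 without Homo 4, and 3 genes changed without Het 1. P450 genes had a median of -0.01 and a mean of -0.15 (camera adjusted p = 0.796, direction higher).

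The gain-of-function set compared virus-borne ARID1A with virus-borne Cre in Rag1-/- livers that carry the MYC transgenes. A difference can come from either virus insert. Of 14074 genes 45 changed, 39 higher and 6 lower after ad-ARID1A. The P450 genes Cyp2a4 (3.66 ± 0.55 SE, adjusted p = 0.0313) and Cyp2b9 (3.28 ± 0.34 SE, adjusted p = 0.00589) had the largest rises among separated genes. Cyp2b9 (chromosome 7, 26173411 to 26210661) was at 0.10 ± 0.17 after ad-Cre and 3.37 ± 0.61 after ad-ARID1A (n = 3 each). Cyp2a22 rose by 2.02 ± 0.31 SE, the lipase inhibitor G0s2 by 2.03 ± 0.29 SE, the fatty aldehyde dehydrogenase Aldh3a2 by 1.93 ± 0.24 SE, Sema5b by 2.09 ± 0.35 SE and BB365896 by 2.17 ± 0.36 SE. Dbp (chromosome 7, 45705088 to 45710203), a transcription factor of the circadian output whose exons overlap the antisense gene Sphk2, rose from 4.04 ± 0.13 to 6.02 ± 0.34 (1.97 ± 0.16 SE, adjusted p = 0.00234). Npas2, a circadian activator of the opposite phase, fell by 2.13 ± 0.36 SE (adjusted p = 0.0486). Moxd1 fell by 5.90 ± 0.89 SE (adjusted p = 0.0313), from 5.95 ± 2.37 to 0.05 ± 0.08, the adhesion receptor Celsr1 by 1.18 ± 0.17 SE and the replication factor Mcm10 by 0.75 ± 0.09 SE.

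**Figure D3:**
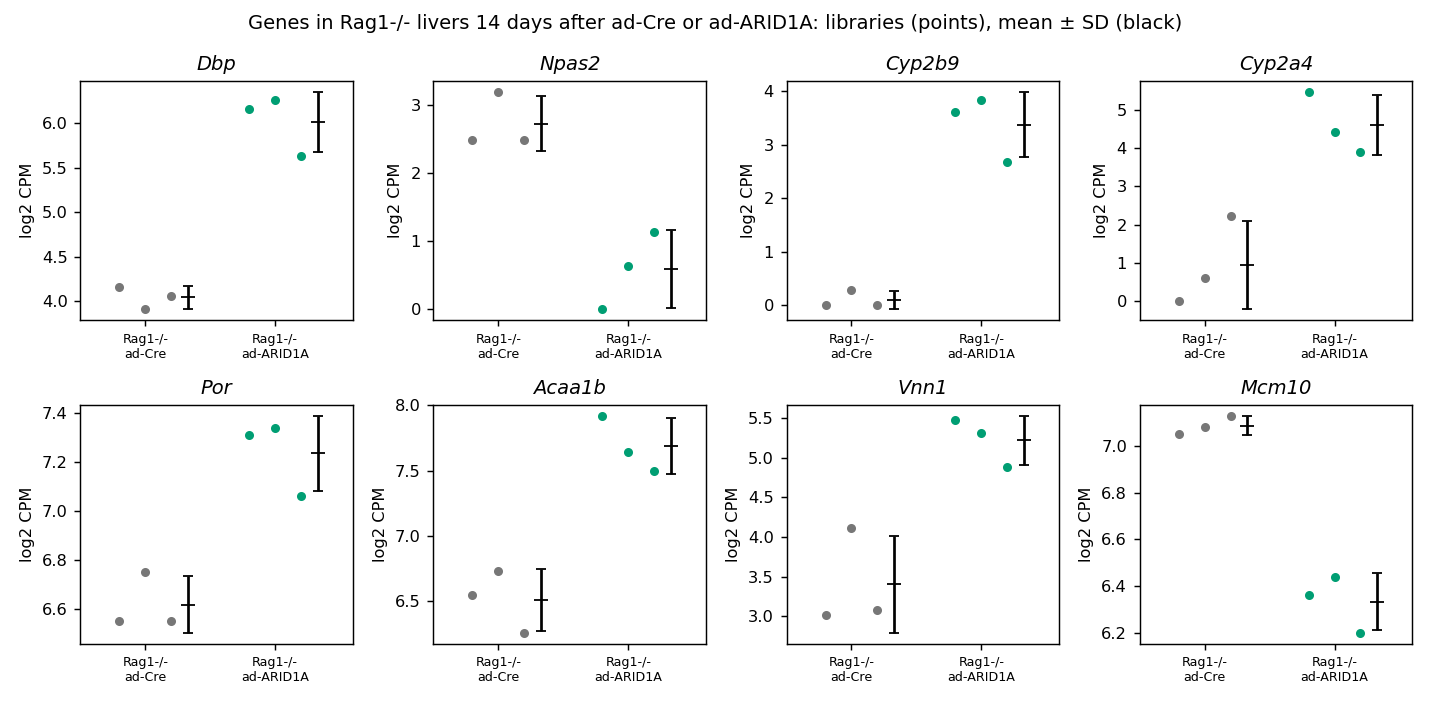
Log2 CPM of 8 genes in the 3 ad-Cre and 3 ad-ARID1A Rag1-/- livers (points), with the group mean ± SD in black; values of 0 are genes at or below 1 CPM. Dbp averaged 4.04 after ad-Cre and 6.02 after ad-ARID1A, and Mcm10 7.09 and 6.33.

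After ad-ARID1A fatty acid oxidation genes were higher in 24 of 24 members, 2 over all genes and 9 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 1.92e-07; adjusted p = 0.512 with an estimated correlation). The 2 were Acaa1b (1.17 ± 0.14 SE, adjusted p = 0.0133), a peroxisomal thiolase, and Vnn1 (1.82 ± 0.28 SE, adjusted p = 0.0313), a pantetheinase. P450 genes were higher in 26 of 32 members, 2 over all genes and 11 adjusted over the list alone, 10 of these higher, with a median of 0.29 (camera adjusted p = 0.00286; adjusted p = 0.547 with an estimated correlation). The 2 were Cyp2b9 and Por (0.62 ± 0.10 SE, adjusted p = 0.0465), the reductase that feeds electrons to P450 enzymes. Acute phase genes were lower in 16 of 23 members, 0 over all genes and 6 adjusted over the list alone, with a median of -0.27 and the fibrinogen genes Fgg (-0.56 ± 0.13 SE) and Fga (-0.56 ± 0.14 SE) among the 6 (camera adjusted p = 2.21e-08; adjusted p = 0.512 with an estimated correlation). Hepatocyte function genes had a median of -0.08, 24 of 37 lower, with Sds (-0.79 ± 0.15 SE) and Gys2 (0.51 ± 0.11 SE) adjusted over the list alone in opposite directions (camera adjusted p = 0.00133; adjusted p = 0.512 with an estimated correlation). The study's genes stood at 0.28 ± 0.20 SE (Emilin1), 0.38 ± 0.15 SE (Mat1a), -0.40 ± 0.47 SE (Lcn2) and -0.33 ± 0.29 SE (Il1r1), with 0 passing either way (camera adjusted p = 0.95).

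Lipogenesis and sterol genes were called lower after ad-ARID1A (19 of 27 lower, median -0.14, Sqle -0.49 and Fdps -0.83). Interferon genes (26 of 27 higher, median 0.45, Mx2 0.76 and Usp18 0.67), stellate cell and fibroblast markers (12 of 14 higher, median 0.46, Dcn 0.45 and Lum 0.77), invasion and matrix genes (19 of 23 higher, median 0.24, Lgals1 1.42 and Snai2 1.05) and cell cycle genes (36 of 41 higher, median 0.40, Tk1 0.66 and Tpx2 1.02) were called higher with 0 members adjusted over the list alone. Endothelial markers were higher in 12 of 13 members with a median of 0.25, and Emcn (1.34 ± 0.32 SE) and Pecam1 (0.39 ± 0.12 SE) passed adjusted over the list alone. Camera adjusted p-values of these 6 lists ran from 4.4e-06 to 0.0356, and with an estimated correlation the smallest was an adjusted p = 0.547 and the largest an adjusted p = 0.746. In all, 10 of 22 lists were called, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry (5 at an unadjusted p under 0.05). The count of 45 was 22 with quantile normalization, 1 without the variance trend and 8 with the sex covariate. In limma, 923 genes had an unadjusted p under 0.05 with the sex covariate and 1759 without it. The labels do not give the sex of the mice, so a difference in sex between the 2 groups of livers stays open for these genes. Of the 10 lists, acute phase, fatty acid and hepatocyte genes stayed called without any single library, and P450 genes were not called without ad-Cre 1 (median 0.24, camera adjusted p = 0.253). Without ad-Cre 1, 2 and 3 the count of genes was 6, 15 and 8, and without ad-ARID1A 1, 2 and 3 it was 0 (1230 at an unadjusted p under 0.05), 7 and 19. With 3 livers against 3, chance separates 10% of genes and 17.4% were separated.

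**Figure D4:**
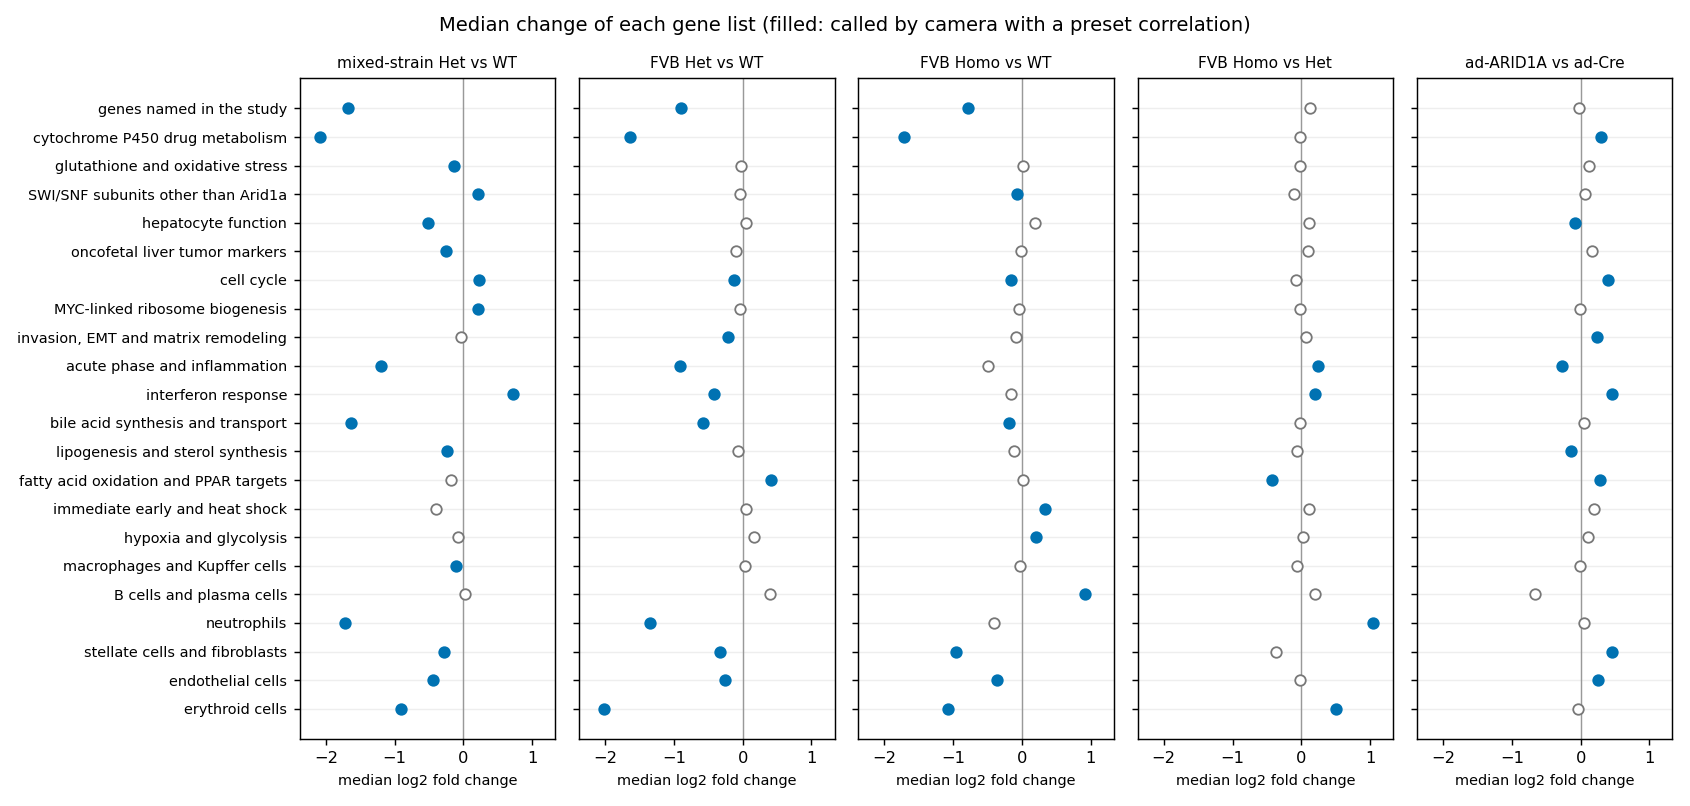
Median log2 fold change of the measured members of 22 gene lists (vertical axis) in the 5 comparisons (panels); filled points are lists called by camera at the preset correlation and open points lists that were not, and none was called with an estimated correlation. The P450 median was -2.08, -1.65 and -1.72 in the 3 comparisons with WT tumors, -0.01 in FVB Homo against Het and 0.29 after ad-ARID1A.

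The sets were then compared with each other in 3 correlations across genes, which are not independent replicates. Mixed-strain Het and FVB Het changes correlated at r = 0.33 (rho = 0.11, 15098 genes), and 0 of the genes that changed were shared, against 0.00556 lower genes for independent lists. Separated genes made up 0.137% of genes in the mixed-strain set (chance 0.0155%) and 6.88% in FVB Het (chance 2.86%), and D16Ertd472e, lower in both, was the 1 gene separated in both. FVB Het and Homo changes correlated at r = 0.783 (rho = 0.683, 16140 genes). These 2 share their WT libraries, and unchanged groups simulated with each gene drawn independently gave r = 0.499 (0.468 to 0.525 over 100 draws). Real genes vary together, which can spread r more widely than these draws. They therefore cannot show that 0.783 exceeds what shared WT libraries give. The covariance was 0.171 against 0.0536 in the simulation, and with the WT libraries split it was 0.111 and r = 0.424 over 6 splits. Orm1 and Apol9a were lower in both FVB comparisons, 2 shared genes against 0.00124 for independent lists, and 7 lists were called lower in both, against 3.52. Independent lists leave out the shared WT libraries. In 100 draws of unchanged groups with the genes' residual covariance, the lower genes shared had a median of 0 and a mean of 4.43 (highest 391), with 2 or more in 2 draws. The lower lists shared had a mean of 1.88 (highest 7), with 7 in 1 draw. With the WT libraries split, the 6 splits shared 0 to 1 lower genes and 2 to 5 lower lists, with 2 WT libraries in each comparison. Changes after ad-ARID1A and in FVB Homo tumors did not correlate (r = -0.02, rho = -0.02, 13321 genes). Of 27 P450 members measured in all comparisons 26 were lower in each of the 3 comparisons with WT tumors, and 21 of these 26 were higher after ad-ARID1A, a count for which no test was run. The 21 ran from 0.01 (Cyp2j5) to 3.82 (Cyp4a14) after ad-ARID1A, where the median of all genes was itself 0.09, so some of them lay below it.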

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

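The test of a library's gap to the rest of its group was planned, and no cause was tested for the values in this part. It was run on 340 groups of values of named genes and list means (log2 CPM), and 38 of them (11.2%) held a library farther from the rest than the test allows, where chance gives about 1 in 20. Genes and lists share libraries, so these are not independent. The rate of 1 in 20 also assumes values without a floor. A library above 0 is always flagged when all others of its group are at 0, whatever its value. This was so for Lrat, Apol9a, Csf3r and Clec4g in FVB Het and for Orm1, Epb42 and Psma8 in FVB Homo tumors. The 11.2% can therefore not be read as an excess over chance.

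In the mixed-strain WT group, Arid1a was 8.94 in WT 7 against 8.30 to 8.53 in the other libraries, and Myc was 5.59 in WT 4. The list means of WT 2 lay above the rest of its group for hepatocyte function (8.22), bile acid synthesis and transport (7.30), acute phase genes (6.55) and glutathione genes (6.31).

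In the mixed-strain Het group, Arid1a was 8.37 in Het 6. Het 5 was highest for Myc (5.95), Cd109 (4.95), Oasl1 (6.74) and the interferon list (6.03). Het 2 was highest for Cyp2c39 (1.47), Thrsp (6.02) and Clec4f (4.48). Het 7 was highest for Slc4a1 (7.24), the erythroid list (4.22) and the neutrophil list (2.32).

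Among the FVB WT tumors, WT 3 was lowest for Ccne1 (4.82), the cell cycle list (5.98) and the SWI/SNF list (5.32). WT 4 was highest for Cdh1 (8.67) and WT 2 for the stellate cell list (5.13). Among the FVB Het tumors, Myc was lowest in Het 2 (3.62) and Smarca2 in Het 4 (3.85). Single libraries lay above others at or near 0 for Lrat (0.29 in Het 4), Apol9a and Csf3r (0.25 each in Het 1), Clec4g (0.60 in Het 2) and the neutrophil list (0.11 in Het 3).

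FVB Homo 3 was highest in its group for Il1r1 (4.59), Orm1 (1.27), Epb42 (1.14), Slc4a1 (4.72) and the neutrophil list (3.58), and lowest for Cdh1 (7.78). Tgfbi was lowest (1.61) and Psma8 highest (2.42) in Homo 2, and Nhs was highest in Homo 4 (0.49).

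The direct test of FVB Homo against Het tumors, which share their WT group, called 5 lists with camera at the preset correlation and 0 with an estimated correlation. Their median log2 fold changes were 0.24 for acute phase genes, 0.20 for interferon genes, -0.42 for fatty acid oxidation genes, 1.03 for neutrophil markers and 0.50 for erythroid markers. FVB Homo 3 held the highest neutrophil mean of its group. Without it 4 lists were called, of which 2 were among the 5, the interferon and fatty acid lists. The neutrophil median was then 0 (camera adjusted p = 0.605), the erythroid median 0.21 (0.605) and the acute phase median 0.13 (0.111).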

How the results depend on the processing

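The runs without FVB WT 1 and 2 and without mixed-strain WT 2 and Het 5 were chosen after seeing the data; the other alternatives were planned. The cause was not tested for any change below except where the alternative itself gives it. Results that stayed on their side of the threshold with their direction, over all alternatives, numbered 2077 of named genes and 445 of called lists in the mixed-strain comparison, 751 and 184 in FVB Het against WT, 749 and 157 in FVB Homo against WT, 472 and 72 in FVB Homo against Het, and 606 and 109 after ad-ARID1A. Those that dropped below the threshold numbered 43 and 14, 36 and 19, 68 and 28, 0 and 7, and 117 and 21. Each gene or list counts once per alternative. The gene counts that stayed include genes that passed in neither fit, as all 472 in FVB Homo against Het. Only genes that had passed can drop, so the 2 gene counts do not give the share of passing genes that kept their call.

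The mixed-strain count of 28 genes was 14 with no filter (13 shared), 75 with the replicate block (21 shared), 101 with array weights (28 shared) and 16 without WT 2 and Het 5 (14 shared). The block tests numbers that do not pair the libraries: libraries with the same number correlated at -0.118 to 0.242. The FVB Het count of 4 was 0 with a mean log2 CPM of at least 2 and with the block (limma, 1689 and 2491 genes at an unadjusted p under 0.05), 1 with only the 2 groups in the fit, 2 with quantile normalization, 2287 with array weights, 41 with the sex covariate and 1 without FVB WT 1 and 2 (0 shared), where its 12 lists were 11 (7 shared). The FVB Homo count of 7 was 0 with a mean of at least 2, with only the 2 groups and with the sex covariate (limma, 1117, 1336 and 1234 at an unadjusted p under 0.05), 1 with the block, 21 with array weights and 3 without FVB WT 1 and 2 (1 shared). Its 11 called lists were 7 with a mean of at least 2 and 7 without FVB WT 1 and 2 (3 shared), with fewer genes or samples tested, and 12 with quantile normalization (2 higher, 10 lower). FVB Homo against Het gave 0 genes under every alternative other than leaving out Het 1. After ad-ARID1A the 45 genes were 22 with quantile normalization (21 shared), 1 without the variance trend and 8 with the sex covariate (7 shared), and the 10 lists were 6 with a mean of at least 2. "No filter" removed or added no gene in the FVB and Rag1-/- tables, so it tests nothing there. The correlation of mixed-strain and FVB Het changes was 0.33 as Pearson's r and 0.110 as Spearman's rho.

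Leaving out 1 library at a time gave 8 to 138 genes (15 to 19 lists) in the mixed-strain comparison, 0 to 256 (10 to 13) in FVB Het, 0 to 36 (10 to 12) in FVB Homo, 0 to 3 (4 to 10) in FVB Homo against Het and 0 to 19 (8 to 10) after ad-ARID1A. The mixed-strain count was 11, 13, 14, 10, 48 and 10 without WT 1, 3, 5, 6, 7 and 8, and 8, 138, 9, 18, 8 and 65 without Het 1, 2, 3, 4, 6 and 7. FVB Het gave 21, 0, 1 and 256 genes without WT 1, 2, 3 and 4, and 0, 0 and 169 without Het 2, 3 and 4. FVB Homo gave 24, 0, 0 and 36 without WT 1, 2, 3 and 4, and 0 without Homo 1, 2 and 4. FVB Homo against Het gave 3 genes and 9 lists without Het 1, and 8 and 10 lists without Homo 1 and 4. The ad-ARID1A count was 6, 15 and 8 without ad-Cre 1, 2 and 3, and 0, 7 and 19 without ad-ARID1A 1, 2 and 3. In limma, leave-one-out runs with 0 genes had 981 to 2311 at an unadjusted p under 0.05 in the comparisons with FVB WT, and 1230 after ad-ARID1A. The correlations ranged from 0.262 to 0.381, from 0.725 to 0.840 and from -0.038 to 0.00926, the last reversed without FVB Homo 3. No alternative moved the median of all genes by over 0.1, and the largest move was after ad-ARID1A, from 0.09 to -0.00333 with quantile normalization.

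Apart from the erythroid list and a correlation, reversed values were of genes that did not pass over all genes. In FVB Het, Myc was -0.0544 with array weights and -0.12 to 0.13 leaving out 1 library. In FVB Homo, Myc was -0.0765 with array weights, -0.000568 with the sex covariate and -0.16 to 0.10 leaving out 1 library, and Ighm ranged from -0.40 to 0.0933. Without FVB WT 1 and 2, FVB Homo gave Il1r1 0.04, Smarcd2 0.005, Ighm 0.49, Slc4a1 0.63, Hbb-bs 0.45 and an erythroid median of 0.45. In FVB Homo against Het, Myc was 0.0149 with quantile normalization and -0.11 to 0.0608 leaving out 1 library, and Arid1a was 0.14 with array weights, 0.0195 with the sex covariate and -0.11 to 0.11 leaving out 1 library. Emilin1 ranged from -0.24 to 0.0867 and Mat1a from -0.27 to 0.0825. After ad-ARID1A, Arid1a was -0.024 and Lcn2 0.25 with the sex covariate, and leaving out 1 library gave Il1r1 -0.56 to 0.0233 and Lcn2 -0.81 to 0.26. Depth limits low genes most in the mixed-strain libraries (2.28 to 5.29 M reads).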

Other observations

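The hepatocyte-share tests for both strains and the hepatocyte median after ad-ARID1A were chosen after the values they explain were seen, as were the clock genes; an earlier FVB test on the hepatocyte function median (0.05 and 0.19) was dropped because the high level of those genes in tumors would hide a small share of liver tissue. Beyond Dbp and Npas2, other circadian clock genes changed between ad-Cre and ad-ARID1A livers. The 12 clock output genes looked at were put together after Per3, Dbp, Tef, Usp2 and Bhlhe40 had been seen, and no test of the group was run. All 12 were higher after ad-ARID1A, with a median of 1.07, 5 did not pass and 7 did: Usp2 (1.88 ± 0.28 SE), Per3 (1.46 ± 0.12 SE), Bhlhe40 (1.11 ± 0.15 SE), Tef (1.03 ± 0.09 SE), Nr1d1 (0.97 ± 0.15 SE) and Hlf (0.51 ± 0.08 SE), with Dbp. Per and Nr1d genes repress the clock, and Dbp, Tef and Hlf are PAR bZIP factors that drive daily expression of liver P450 genes.

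A difference in the time of day at which livers were collected may account for the clock genes. It predicted that genes of the opposite phase fall, and the median of 5 such genes was -0.52, close to the bound of -0.5 set for it, with Npas2 (-2.13) passing and Arntl (-1.22), Cry1 (-0.52), Clock (-0.17) and Nfil3 (-0.02) not. Without Npas2 the median of the other 4 was -0.345, short of the bound, so the test decides little. More hepatocytes in the ad-ARID1A livers would raise the hepatocyte function list, and its median was -0.08. These genes are already abundant in whole liver, so a higher share could move the list little, and this median cannot decide it. The labels give no collection time, and an effect on the clock of ARID1A, or of Cre in the control livers, stays open and untested. Because PAR bZIP factors act on P450 genes, the rise of P450 genes after ad-ARID1A is open in the same way.

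P450 genes were lower in FVB Het and Homo tumors than in FVB WT tumors, and a higher share of non-tumor liver in the WT samples may account for part of it. The fall of 14 P450 genes would need a median of 3.21% of liver RNA in the WT samples, and 149 other genes abundant in ad-Cre livers and low in tumors needed a median of 2.68% (quartiles 1.25% and 4.18%, 134 of them above 0). A single share would be about the same in every gene. Some genes abundant in ad-Cre livers differed from it, with 0.00195% for Serpina1e, 0.535% for Scd1, 0.661% for Aox3, -1.88% for Ahsg and -6.01% for Plg. A negative value means a higher level in Homo tumors (Plg, mean CPM 148 in WT and 269 in Homo), which a share of liver in WT cannot give or exclude. The ad-Cre livers also came from other mice. Single genes therefore cannot decide it, and it stays open. The 2 FVB WT libraries that stand apart do not account for it, since the P450 median of FVB Homo tumors was -1.61 without them. In the mixed-strain tumors the hepatocyte function list was lower with the P450 genes (median -0.51), which also goes with more non-tumor hepatocytes in WT samples or with less differentiated Het tumors. Genotype, age and Cre stay open, untested.

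Abundant short genes read lower in the mixed-strain table than in the FVB table, which may come from duplicate reads removed before counting. Across 248 genes with at least 1000 reads per kb in FVB, the ratio of the tables fell with reads per kb (rho = -0.68), against 0.0559 over 12041 genes of 10 to 1000 reads per kb. The FVB value is part of the ratio, and 1000 shuffles of the mixed-strain reads per kb over the same genes gave a median rho of -0.702 (-0.786 to -0.593), so duplicate removal and a strain difference in expression cannot be told apart by the rho of -0.68. Shuffles of CPM gave a median of -0.344 (-0.466 to -0.234), a range that the rho of -0.68 lies beyond. They also break the tie of CPM to gene length, so they do not decide it. Against the mean of both tables the rho was -0.549. The highest gene had 3287 reads per kb in the mixed-strain table and 751273 in the FVB table.

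Other splits of the same libraries were tested against each count. For the mixed-strain count of 28 genes, 2 of 100 splits, the real one included, gave as many, a share under 0.05 in this draw. The other of these 2 splits gave 46 genes. Only 100 splits were drawn and the shares were not adjusted for the number of counts tested, so this is weak evidence against chance. For its 17 lists 16 of 100 splits gave as many (highest other 20), and for its correlation with FVB Het 7 of 100 were as far from 0 (highest other 0.467), so chance cannot be excluded. Nor can it for the 4 genes (2 of 35 splits, highest other 5) and 12 lists (10 of 35, highest other 15) of FVB Het, or the 7 genes (3 of 35, highest other 13) and 11 lists (11 of 35, highest other 16) of FVB Homo. The same holds for FVB Homo against Het, with 0 genes (35 of 35, highest other 4) and 5 lists (34 of 35, highest other 14), and for the correlation of ad-ARID1A with FVB Homo (28 of 35, highest other 0.0778). For ad-ARID1A the 10 splits are too few for a share under 0.05: 45 genes changed (1 split, highest other 3) and 10 lists were called (2 splits, highest other 10).

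Of the lists that were called in no comparison, p53 targets had medians of 0.19 (mixed-strain), -0.16 (FVB Het), 0.02 with a mean of -0.05 (FVB Homo), 0.11 (FVB Homo against Het) and 0.29 (ad-ARID1A), with camera adjusted p from 0.111 to 0.803. Biliary and progenitor markers had medians of 0.06, -0.13, -0.17, -0.12 and 0.54, with camera adjusted p from 0.149 to 0.96 and a test direction opposite to the median in FVB Homo and in FVB Homo against Het. T and NK cell markers had medians of 0.12, -0.08 (mean 0.02) and -0.02 in the comparisons with WT, with camera adjusted p from 0.539 to 0.661. In the Rag1-/- livers T and NK cells (2 measured), B and plasma cells (1 measured) and neutrophils (2 measured) were not tested. Pancreatic acinar cells had 1 measured member, not tested, at -0.57, 0.34, 0.65, 0.31 and 0.04.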
